A study of Rattus norvegicus with 9 samples.

How the data were processed

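RNA from the pubococcygeus muscle of rats was sequenced, with 9 libraries, 3 in each of 3 groups. The sources used here do not say how the 3 libraries of a group relate to its 8 rats beyond numbering them, so p-values measure the spread between these libraries. All 9 libraries carry one batch label. Group and replicate number were taken from the sample titles. The library names call the untreated SUI group sham, while the titles describe the full model, and the titles were followed.

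The submitters' processing notes name Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 and the genome build mRatBN7.2. Whether reads were counted by strand is not given in the sources used here. The deposited expected counts are whole numbers, per the file headers and values, and look rounded up: 358 values of 1 stand beside an FPKM below 0.001. The deposited FPKM values, per the file headers, are fragments scaled by gene length and library size, as estimated by the authors, and were used for alternatives and to derive gene lengths. The tables hold 30518 rows, of which 4341 have no symbol and 916 share an Ensembl ID with another row. Rows were kept as deposited, and where rows shared a symbol the one with the highest mean count kept it. Symbols of the gene lists were matched to the rows, with older symbols looked up in a RefSeq table of the GRCr8 assembly used for names only. Of 1009 list members, 963 matched a row and 929 were tested. Members without a match, such as Myh1 and Myh4, are not analysed here.

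Counts were filtered with filterByExpr, which left 16256 genes, and scaled by TMM factors. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust) with all 9 libraries in one fit and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were taken as the size of the change over the square root of F. Values are given as CPM (counts scaled by TMM-adjusted library size), mean ± SD over 3 libraries, and as edgeR log2 fold change ± SE. The mean shift of a list is the difference between groups in its mean log2 CPM. The 51 gene lists fixed before the data were examined were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, for lists with at least 5 tested genes. None of the list calls in the 3 comparisons held with an estimated correlation, where the lowest adjusted p were 0.606, 0.715 and 0.392. The rotation test fry, which asks whether a list moves on balance one way, called 0 lists in each comparison, and its mixed form, for change in either direction, 4, 4 and 0. Splits of the same libraries other than the real one gave up to 18, 27 and 24 list calls at the preset correlation, against 15, 15 and 7 for the groups.

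The tests, their samples and the gene lists were set before the data were examined, as was the rule for named genes. It takes, for each comparison with SUI, the 10 largest rises and 10 largest falls among genes past the threshold with a mean CPM of at least 1, no overlap between groups and a symbol that is not only an identifier, filled to 5 per direction by smallest p where fewer than 5 pass. Up to 4 members of each described list by smallest p are added, and so are Myh7, Myh2, Myh1, Myh4, Myh3, Fbxo32, Trim63, Col1a1, Col3a1, Ppargc1a and Esr1. For stimulated against blank the limit is 5 per direction, and up to 10 genes called in opposite directions would be named, of which there were 0. Further genes, such as Lox, Bmal1, Musk, Mmp9 and Spata6l where the rule does not reach them, were named after their values were seen.

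Alternatives were DESeq2 size factors, library totals without composition factors, no filter, a filter at a mean CPM of 1, DESeq2 1.42.0, voom with sample weights, fits on the 6 libraries compared, a replicate block, limma on log2 FPKM with pseudocounts of 1 and 0.1, and leaving out each library. Further alternatives were added after the data were seen. With library totals only, the median log2 fold change of all genes moved to 0.19, -0.11 and 0.09 in the 3 comparisons, and changes are given relative to the TMM scale. The edgeR, DESeq2 and camera steps were tested on simulated data with 200 genes changed by known folds. A list of 25 genes raised 2-fold was called and 0 of 50 unchanged lists were. Each gene was simulated independently, so this says nothing of list calls where genes correlate. Depth ran from 50833480 to 147650284 counts per library, where 3 counts correspond to 0.021 to 0.0794 CPM, a floor that covers counting error only.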

Results

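Gene expression was measured by RNA sequencing in the pubococcygeus, a striated muscle of the pelvic floor, of female Sprague-Dawley rats. The study randomised 24 rats to 3 groups of 8, and 3 libraries per group, 9 in all, were used here. Blank rats were left untouched. Rats of the SUI group, named for stress urinary incontinence, had both ovaries removed and the vagina distended by an 8 Fr balloon catheter filled with 3 mL of saline and pulled by a 120 g weight for 4 h. Rats of the stimulated group (SUI with PFES, pelvic floor electrical stimulation through the vagina) had the same procedure and, from 1 week later, pulses of 50 Hz, 20 mA and 200 µs for 30 min on 5 days a week over 2 weeks. The SUI and stimulated groups therefore share the operation, and no group that was operated on without distension or ovary removal was part of the comparison. SUI rats had no additional treatment, per the sample titles, and no group had a sham stimulation. The current and the handling that goes with it therefore cannot be told apart. Total counts per library ran from 50833480 in blank replicate 1 to 147650284 in stimulated replicate 1, with a median of 110699836, and 16256 genes passed the filter on low counts.

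Blank replicate 1 stood apart from the other 8 libraries. Transcripts of the mitochondrial genome took 32.9% of its counts, against 13.4% to 17.7% elsewhere, and its median correlation with the other libraries over genes was 0.920. SUI replicate 1 came next at 0.949, and the remaining 7 lay between 0.954 and 0.968. The principal component with the largest share of variance, 31.5%, separated blank replicate 1 from the rest. In blank replicate 1 the shortest of 5 equal classes of genes, with a median length of 1.24 kb, lay 0.379 log2 units below the mean of the 9 libraries, and the longest, with a median of 6.88 kb, 0.19 above.

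The first comparison asked what the model did to the muscle, SUI over blank. Collagen and matrix genes were lower in SUI: 24 of the 27 measured had a negative log2 fold change, with a median of -1.08. Col1a1, the main chain of fibrillar collagen type I, averaged 62.4 ± 20.5 CPM in SUI against 308 ± 63.7 in blank (SD, n = 3), and Thbs1, which encodes a matrix glycoprotein, 5.03 ± 0.263 against 11.8 ± 2.81. Atrophy genes, the ubiquitin ligases and autophagy genes of wasting muscle, were higher, with 18 of 20 positive and a median of 0.70. Gadd45a, a stress-response gene, averaged 55.3 ± 4.23 CPM in SUI and 23.7 ± 4.17 in blank. No single gene passed the threshold over all genes tested with edgeR.

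As a set, the collagen and matrix genes fell (camera adjusted p = 2.21e-14, preset correlation), but adjusted p = 0.606 with an estimated correlation. With edgeR, 11 of the 27 passed adjusted over the list alone, all lower in SUI, and 0 did so over all genes tested. Those with the smallest p were Thbs1 (log2 fold change -1.22 ± 0.21 SE), Tnc (-2.35 ± 0.49), Fbn1 (-1.60 ± 0.35) and Col1a1 (-2.30 ± 0.58). Fibro-adipogenic progenitor markers, genes of the connective tissue cells of muscle, moved in the same direction, with 10 of 12 negative (adjusted p = 0.0238, and adjusted p = 0.64 with an estimated correlation). The call of the progenitor markers was lost without blank replicate 3 (0.0934) or SUI replicate 3 (0.0674), and 0 of these 12 passed adjusted over the list alone. Tendon, cartilage and bone markers fell too, with 14 of 15 negative and a median of -1.96 (adjusted p = 2.66e-05, and adjusted p = 0.606 with an estimated correlation). Ibsp, a bone matrix gene, was uneven within the blank group, at 14.1, 0.906 and 1.87 CPM.

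Atrophy genes rose as a set (camera adjusted p = 8.64e-05, and adjusted p = 0.606 with an estimated correlation), and without blank replicate 1 and SUI replicate 1 together the adjusted p was 0.226. Atrophy genes had a mean shift of 0.64, and 0.38 without SUI replicate 1. Of its 20 members, only Gadd45a passed adjusted over the list alone. Fbxo32, which encodes the muscle ubiquitin ligase atrogin-1, measured 583, 74.8 and 138 CPM in the SUI libraries against 33.7 to 87.5 in blank, and its log2 fold change was 2.21 ± 0.69 (edgeR adjusted p = 0.524). Trim63, the other classical atrophy ligase, had a log2 fold change of 0.71 ± 0.63 (edgeR adjusted p = 0.733). Glucocorticoid-responsive genes also rose, with 18 of 20 positive and a median of 0.94 (camera adjusted p = 0.000266, and adjusted p = 0.606 with an estimated correlation). Glucocorticoid-responsive genes had a mean shift of 0.83, and 0.49 without blank replicate 1. The receptor itself, Nr3c1, went the other way at -0.97 ± 0.24. Cytosolic ribosomal protein genes rose by a median of 0.42 (adjusted p = 2.88e-07, and adjusted p = 0.606 with an estimated correlation), and the blank replicate 1 mean of this list lay 0.829 log2 units below the 9-library mean. Without that library the mean shift of the ribosomal genes was 0.21, against 0.48 with it.

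Circadian clock genes fell on balance, with 12 of 18 negative (camera adjusted p = 0.0114, and adjusted p = 0.606 with an estimated correlation). Adjusted over the list alone, 5 passed and all were lower, among them the repressor Nr1d1 (-2.20 ± 0.45) and Bhlhe40 (-2.06 ± 0.42). Without blank replicate 3 the adjusted p of the clock genes was 0.088, and without SUI replicate 2 that of the nerve markers, given next, 0.0679. Peripheral nerve markers fell, with 13 of 15 negative (adjusted p = 0.000444, and adjusted p = 0.606 with an estimated correlation), as did leukocyte and antigen presentation genes, with 13 of 17 negative (adjusted p = 0.0017, and adjusted p = 0.606 with an estimated correlation). Leukocyte genes had a mean shift of -0.62, and -0.40 without blank replicate 2. Transcripts of the mitochondrial genome fell (adjusted p = 0.000307, and adjusted p = 0.606 with an estimated correlation), and without blank replicate 1 the value was 0.0526 and the mean shift -0.24, against -0.82 with it. TGF-beta and fibrosis genes, Wnt and Hippo genes, complement genes and erythroid markers were called lower, and oxidative stress response genes higher, with camera adjusted p from 0.00564 to 0.0455 and adjusted p = 0.606 to 0.63 with an estimated correlation. The TGF-beta call was lost without blank replicate 3 (0.0686) or SUI replicate 3 (0.109), that of oxidative stress genes without blank replicate 1 (0.184) or SUI replicate 1 (0.243), and that of complement genes without blank replicate 2 (0.0923), blank replicate 3 (0.0934) or SUI replicate 3 (0.214). Erythroid markers lost theirs without blank replicate 1 (0.132), blank replicate 2 (0.312), SUI replicate 2 (0.259) or SUI replicate 3 (0.0826), and with DESeq2 size factors or the replicate block (0.0506 each). Their mean shift was -1.06, against -0.67 without SUI replicate 2 and -1.60 without blank replicate 3. With the length trend of each library removed, the clock, TGF-beta and oxidative stress calls were lost (0.0502 each), as was that of complement genes (0.0671). Slow fibre, fast fibre and regeneration genes were not called, and the fixed fibre genes Myh7 (-0.34 ± 0.37) and Myh2 (-0.42 ± 0.32) differed by about their standard error.

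Among single genes, those with the smallest p that were separated between groups, none past the threshold with edgeR, included Myf6. This myogenic transcription factor was at 359 ± 118 CPM in SUI against 73.7 ± 37.2 in blank (2.28 ± 0.38). Hdac4, a deacetylase raised in denervated muscle, was at 26.2 ± 6.89 against 8.08 ± 2.34 (1.70 ± 0.30). On the lower side were Ky, a gene needed for normal muscle growth, at 31.1 ± 17.1 against 207 ± 74.8 CPM (-2.74 ± 0.44), the small GTPase gene Rrad (-2.88 ± 0.44), Ntrk2 (-2.26 ± 0.35), Tmem131l (-1.37 ± 0.19) and Ccn2 (-1.93 ± 0.29). All of these had an edgeR adjusted p of 0.2. Neuromuscular junction and denervation genes were not called as a set (camera adjusted p = 0.158), though Hdac4 and Musk passed adjusted over the list alone.

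With edgeR, 0 genes were called in SUI against blank (1 without stimulated replicate 2). At an unadjusted edgeR p under 0.05 there were 1329 genes (461 higher, 868 lower), against a mean of 813 expected by chance. Leaving out one library gave 1033 to 1930. The other splits of the libraries compared gave 355 to 1248, the highest with blank replicate 3 and SUI replicate 1 exchanged between the groups. A count well above 813 can therefore arise from another grouping of these libraries. None of the other splits reached 1329, but they are too few to judge chance. DESeq2 called 37 higher and 139 lower, and voom with sample weights 0. In simulated counts with no difference between these groups, DESeq2 called 8 genes and edgeR 0. That was a single simulated data set, with genes drawn independently and no library made to stand apart. The 8 is therefore not the number of false calls to expect in these libraries.

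**Figure D1:**
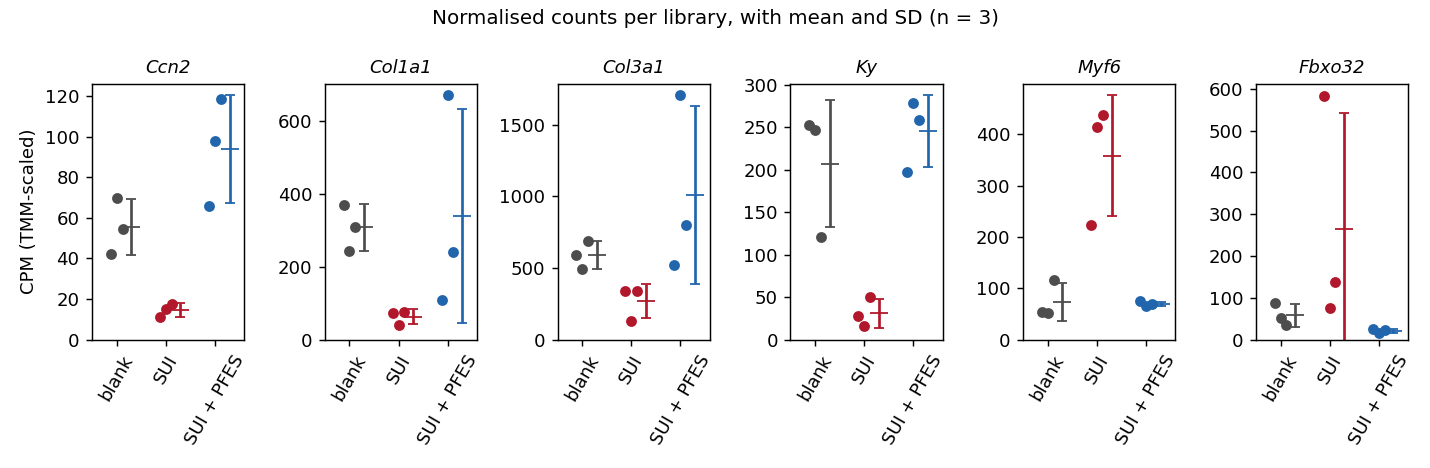
TMM-scaled CPM (linear axis from 0) of 6 genes in each library, as points by group, with the group mean and SD (n = 3) beside them, the SD of Fbxo32 in SUI reaching below the axis. Ccn2 lay at 11.1 to 17.6 in the SUI libraries, and at 65.7 or more in the stimulated libraries.

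The second comparison asked what stimulation did in rats that all had the model, stimulated over SUI. Ccn2, which encodes a secreted matrix protein induced by TGF-beta and by mechanical load, rose from 14.6 ± 3.25 CPM in SUI to 94.0 ± 26.7 after stimulation (SD, n = 3), a log2 fold change of 2.69 ± 0.30. Collagen and matrix genes were higher, with 26 of 27 positive and a median of 1.21: Col3a1 averaged 1010 ± 621 CPM against 271 ± 120, and Thbs1 15.9 ± 1.16 against 5.03 ± 0.263. Atrophy genes were lower, with 19 of 20 negative and a median of -0.66, among them Fbxo32 at 20.8 ± 5.25 against 265 ± 277 CPM. Plpp6, a phospholipid phosphatase gene, fell to a count of 0 in all 3 stimulated libraries, at least 348-fold lower than in SUI when set against a floor of 3 counts over the group.

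Ccn2 (chromosome 1, 20802199 to 20805734, minus strand, mRatBN7.2) and Plpp6 (chromosome 1, 226679100 to 226681949, plus strand) were the 2 genes past the threshold with edgeR, at adjusted p = 0.0444 and 0.0198. Plpp6 lies inside Spata6l, which is annotated on the other strand from 226641518 to 226682884. Spata6l measured 3.76 ± 0.678 CPM after stimulation against 0.406 ± 0.198 in SUI. Reads of any exon sequence that both share could not be told apart without strand, and the exon structure of the overlap was not examined. Ccn2 kept its call without stimulated replicate 1 (adjusted p = 0.0391) and lost it without each of the other 8 libraries (0.0531 to 0.298), while its log2 fold change stayed between 2.49 and 2.90 in all 9 cases. Plpp6 kept its call without blank replicate 3, SUI replicate 2 or stimulated replicate 1 and lost it without each of the other 6 (0.0531 to 0.134).

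Collagen and matrix genes rose as a set (camera adjusted p = 2.34e-14, and adjusted p = 0.715 with an estimated correlation). The mean shift of the collagen list was 1.05, and 0.70 without stimulated replicate 2. Adjusted over the list alone, 18 were higher and 1, the cross-linking enzyme gene Lox (-1.29), was lower. The examples with the smallest p were Thbs1 (1.66 ± 0.21), Col5a1 (1.83 ± 0.36), Lum (1.56 ± 0.34) and Loxl2 (1.56 ± 0.36). Fibro-adipogenic progenitor markers moved with them, with 11 of 12 positive and 4 past the threshold adjusted over the list alone, Mfap5, Cd34, Smoc2 and Clec3b (camera adjusted p = 0.00204, and adjusted p = 0.739 with an estimated correlation). Without stimulated replicate 2 the adjusted p of the fibro-adipogenic progenitor markers was 0.171. In that library their mean lay 1.41 log2 units above the 9-library mean, and in the other stimulated libraries at -0.631 and 0.318. Their mean shift was 0.90, against 0.37 without stimulated replicate 2 and 1.40 without stimulated replicate 1. TGF-beta and fibrosis genes rose (adjusted p = 0.0448, and adjusted p = 0.715 with an estimated correlation), with Ccn2 and Bmp1 past the threshold adjusted over the list alone. The TGF-beta call was lost without blank replicate 1 (0.0715), SUI replicate 3 (0.2), stimulated replicate 2 (0.0914) or stimulated replicate 3 (0.0971), and with length trends removed (0.0559).

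Oxidative phosphorylation genes rose slightly, with 35 of 36 positive and a median of 0.32 (camera adjusted p = 1.83e-05, and adjusted p = 0.739 with an estimated correlation). The mean shift of these genes was 0.34, and 0.18 without SUI replicate 1. Their leading members were Ndufa1 (0.51 ± 0.17) and Cox5b (0.53 ± 0.18), and adjusted over the list alone 0 passed. Citric acid cycle genes rose with 18 of 19 positive (adjusted p = 0.0235, and adjusted p = 0.842 with an estimated correlation), a call lost without SUI replicate 1 (0.521), stimulated replicate 1 (0.469) or stimulated replicate 3 (0.0626). Cell cycle genes rose with 19 of 22 positive, led by Rrm2 and Top2a, both under 1 CPM in every group mean (adjusted p = 0.00192, and adjusted p = 0.715 with an estimated correlation). With the filter at a mean CPM of 1 the cell cycle call was lost (0.0794). Immediate early genes rose with 16 of 20 positive (adjusted p = 0.0117, and adjusted p = 0.739 with an estimated correlation), and Atf3 (2.07 ± 0.56), Btg2 and Fosl2 passed adjusted over the list alone. Without SUI replicate 3 the adjusted p of the immediate early genes was 0.112, and without stimulated replicate 3 it was 0.105.

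Circadian clock genes rose on balance, with 12 of 18 positive (camera adjusted p = 0.0251, and adjusted p = 0.715 with an estimated correlation). Adjusted over the list alone, 7 were higher, led by Bhlhe40 (2.01 ± 0.42) and Ciart (2.08 ± 0.46), and the activator gene Bmal1 was lower (-1.38). The clock call was lost without SUI replicate 3 (0.135), stimulated replicate 1 (0.202) or stimulated replicate 3 (0.0677). Interferon-stimulated genes rose with 21 of 23 positive (adjusted p = 0.0155, and adjusted p = 0.849 with an estimated correlation). Without stimulated replicate 2, whose mean of the interferon-stimulated genes lay 1.61 log2 units above the 9-library mean, they went the other way (adjusted p = 0.411), and without SUI replicate 2 the value was 0.0532. Their mean shift was 0.57, against -0.10 without stimulated replicate 2 and 1.00 without stimulated replicate 1. Leukocyte and antigen presentation genes rose with 16 of 17 positive (adjusted p = 0.0156, and adjusted p = 0.842 with an estimated correlation), a call lost without stimulated replicate 2 (0.882) or SUI replicate 2 (0.0524). The mean shift of the leukocyte genes was 0.59, against 0.09 without stimulated replicate 2 and 1.04 without stimulated replicate 1. Peripheral nerve markers rose with 13 of 15 positive (adjusted p = 0.0117, and adjusted p = 0.739 with an estimated correlation), and Wnt and Hippo genes with 14 of 24 (adjusted p = 0.0448, and adjusted p = 0.739 with an estimated correlation). The nerve call was lost without SUI replicate 2 (0.294) or stimulated replicate 3 (0.059), and the Wnt call without SUI replicate 2 (0.0532), SUI replicate 3 (0.145), stimulated replicate 2 (0.077) or stimulated replicate 3 (0.108), and with the filter at a mean CPM of 1 (0.0639).

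Atrophy genes fell as a set (camera adjusted p = 0.000247, and adjusted p = 0.739 with an estimated correlation), with Fbxo32 (-3.67 ± 0.73) and Gadd45a (-1.01 ± 0.21) past the threshold adjusted over the list alone. Over the whole atrophy list the mean shift was -0.57, against -0.32 without SUI replicate 1, where Fbxo32 was at 583 CPM, and -0.35 without stimulated replicate 2. Unfolded protein response genes fell with 14 of 18 negative, among them Xbp1 (-0.59 ± 0.20) and Atf4 (-0.71 ± 0.25) (adjusted p = 0.0155, and adjusted p = 0.715 with an estimated correlation). Glucocorticoid-responsive genes fell with 16 of 20 negative (adjusted p = 0.0155, and adjusted p = 0.758 with an estimated correlation), among them Angptl4 (-2.74 ± 0.73), while Per1 and Nr3c1 were positive. Without SUI replicate 1 the adjusted p of the unfolded protein response genes was 0.0621, and without stimulated replicate 2 that of the glucocorticoid-responsive genes was 0.301, whose call was also lost with the filter at a mean CPM of 1 (0.0553). Unfolded protein response genes had a mean shift of -0.16, against -0.07 without SUI replicate 1 and -0.29 without SUI replicate 2.

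Other single genes separated between these groups, none past the threshold with edgeR, were Thbs1, Tmem131l (1.41 ± 0.19), Cpa1 (2.75 ± 0.40) and Ky, at 246 ± 42.4 CPM after stimulation (2.98 ± 0.44). On the lower side were Myf6, at 69.5 ± 4.61 CPM (-2.37 ± 0.38), Cd24 (-1.34 ± 0.26), Lrrc30 (-3.13 ± 0.62) and Atf5 (-1.09 ± 0.22). The edgeR adjusted p of these 8 genes lay between 0.0861 for Thbs1 and 0.266 for Atf5. Myh7 (0.32 ± 0.37) and Myh2 (0.22 ± 0.32) differed by less than their standard error and Ppargc1a (0.52 ± 0.41) by little more. The oestrogen receptor gene Esr1 differed by 1.37 ± 0.69.

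In stimulated against SUI rats, edgeR called 1 gene higher and 1 lower (0 to 3 genes without 1 library), with 1300 at an unadjusted p under 0.05. Leaving out one library gave 754 (without stimulated replicate 2) to 2224 (without blank replicate 1) such genes. Another split of the same 6 libraries gave 1596. DESeq2 called 153 higher and 55 lower, and voom with sample weights 32 and 16. Without blank replicate 1, DESeq2 called 368 higher and 216 lower, and voom with sample weights 2 and 0. In counts simulated for this comparison, edgeR recovered 5 of 100 genes changed 2-fold and 67 of 100 changed 4-fold, with 4 false calls, and DESeq2 28 and 89 with 60 false calls.

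**Figure D2:**
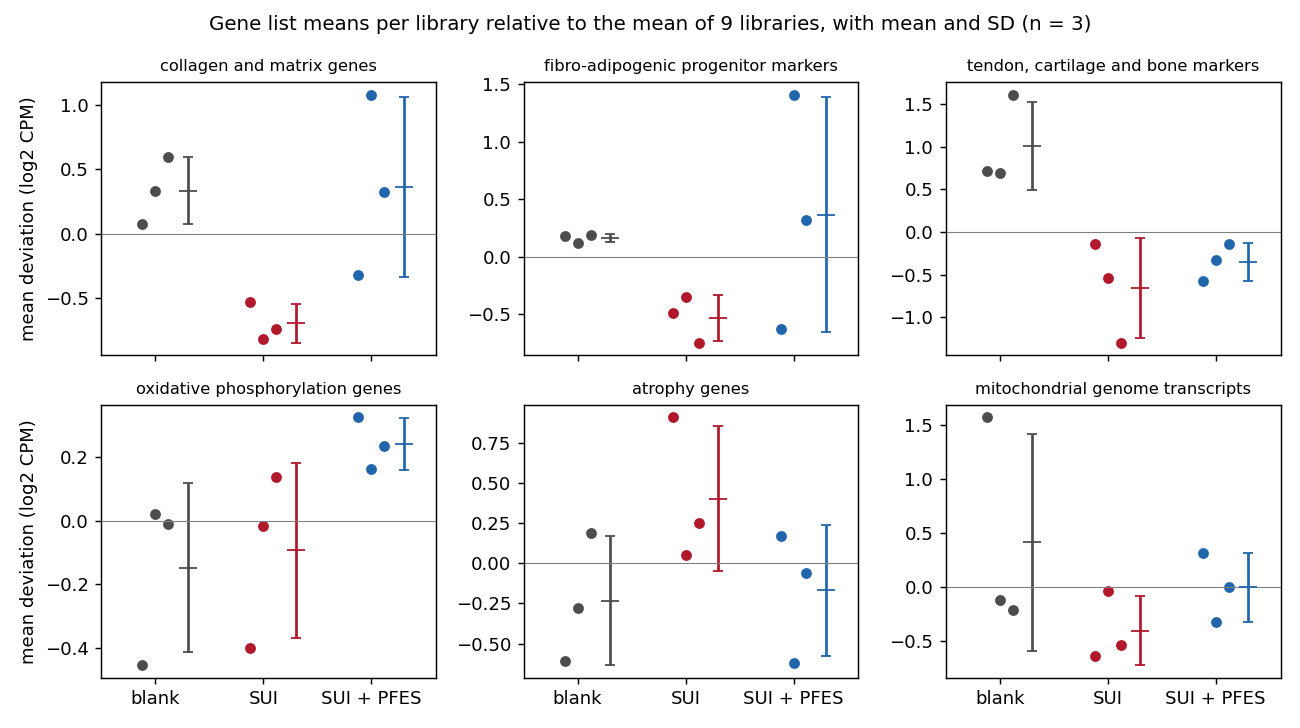
Mean of 6 gene lists per library (log2 CPM relative to the mean of the 9 libraries), as points by group, with the group mean and SD (n = 3) beside them. Collagen and matrix genes lay at -0.819 to -0.526 in the SUI libraries and at -0.318, 1.08 and 0.324 in the stimulated ones, and the mitochondrial genome transcripts of blank replicate 1 at 1.57.

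The last comparison asked how far stimulated rats still stood from untouched ones, stimulated over blank. Ntrk2, a neurotrophin receptor gene, remained low, at 2.95 ± 0.832 CPM after stimulation against 12.2 ± 3.46 in blank (SD, n = 3). It did not pass the threshold with edgeR, while DESeq2 called it (adjusted p = 7.73e-05). Tendon, cartilage and bone markers were lower, with 12 of 15 negative and a median of -1.30, while oxidative phosphorylation genes were higher, with 32 of 36 positive and a median of 0.39. Collagen and matrix genes (camera adjusted p = 0.697) and atrophy genes (0.892) were not called.

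Plpp6 was the 1 gene past the threshold with edgeR (adjusted p = 0.0147), at least 482-fold lower than in blank on the same floor, and the overlapping Spata6l was higher (2.88 ± 0.50, adjusted p = 0.841). The Plpp6 call held without blank replicate 3 or SUI replicate 2 and was lost without each of the other 7 libraries (0.0551 to 0.161). Oxidative phosphorylation genes rose (camera adjusted p = 5.48e-08), as did cytosolic ribosomal protein genes (4.34e-07), and both had adjusted p = 0.807 with an estimated correlation. In blank replicate 1 these lists lay at -0.456 and -0.829 of the 9-library mean, and without it their mean shifts went from 0.39 to 0.24 and from 0.45 to 0.19. Endothelial markers and angiogenesis genes (0.00361) and satellite cell markers (0.0104) rose, with adjusted p = 0.392 with an estimated correlation for both, led by Eng (0.54 ± 0.16) and Notch1 (0.60 ± 0.24). The endothelial call was lost without blank replicate 3 (0.16) and the satellite cell call without stimulated replicate 1 (0.065) and with the filter at a mean CPM of 1 (0.0723). Citric acid cycle genes rose (0.021) and mitochondrial genome transcripts fell (0.0411), with adjusted p = 0.978 with an estimated correlation for both, and without blank replicate 1 the mitochondrial genome transcripts went the other way (0.495). Their call was also lost without each of the SUI libraries in turn (0.0501 to 0.069), stimulated replicate 2 (0.172) or stimulated replicate 3 (0.0728), and the citric acid cycle call without blank replicate 3 (0.0525), stimulated replicate 1 (0.475) or stimulated replicate 3 (0.0535), and with length trends removed (0.0636). The mean shift of the mitochondrial genome transcripts was -0.42, against 0.16 without blank replicate 1, -0.26 without stimulated replicate 2, -0.68 without blank replicate 2 and -0.73 without blank replicate 3.

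Tendon, cartilage and bone markers fell (camera adjusted p = 0.000861, and adjusted p = 0.392 with an estimated correlation), with Ibsp and Acan, a cartilage proteoglycan gene, past the threshold adjusted over the list alone, and the value of the list was 0.0525 without blank replicate 3 and 0.0829 with the filter at a mean CPM of 1. Among matrix turnover genes, not called as a set (0.433), the collagenase genes Mmp13 (-6.71 ± 1.38) and Mmp9 passed adjusted over the list alone. Adgrb2, an adhesion receptor gene separated between the groups, was at 37.7, 24.8 and 0.444 CPM in the stimulated libraries and at most 0.316 in blank (edgeR adjusted p = 0.898). Circadian clock genes were not called as a set (0.892), yet 2 were higher and 4 lower adjusted over the list alone, with Bmal1 at -1.70, Npas2 at -1.65 and Per2 at 0.84. In stimulated against blank rats edgeR called 0 genes higher and 1 lower, with 613 at an unadjusted p under 0.05 against 813 expected. Leaving out one library gave 386 (without stimulated replicate 3) to 1161 (without blank replicate 2) at that level. DESeq2 called 8 higher and 13 lower, and voom with sample weights 1 higher, Spata6l (3.32, adjusted p = 0.011), and 0 lower, with Plpp6 at adjusted p = 0.0542. In simulated counts for these groups DESeq2 made 43 false calls and edgeR 0. Those counts held 200 changed genes and a raised list of 25, so 43 is not the number expected of unchanged groups.

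The 2 comparisons that share the SUI libraries ran in opposite directions for many genes. At an unadjusted p under 0.05 in both, 389 genes were lower in SUI and higher after stimulation, as for Ccn2, Ky and Tmem131l, and 167 were higher and then lower, as for Myf6, Gadd45a and Fbxo32. The same direction in both was seen for 2 genes, and for 0 to 5 in the simulations of unchanged groups given below. That count therefore does not speak for an effect. The total of 556 became 345 without stimulated replicate 2 and also without stimulated replicate 3, 842 on the 7 libraries without blank replicate 1 and SUI replicate 1, and 1174 with voom sample weights. Of these 556 opposite genes, 0 were called in both comparisons after adjustment with edgeR, and 74 were with DESeq2. The SUI libraries enter both comparisons, so opposite signs arise with no effect. In 40 simulations of unchanged groups 156 to 198 genes were opposite, with a mean of 174, and independent lists would give 58.2. Each gene was simulated independently, so this range is narrower than that of real libraries. Other drawn splits of the 9 libraries gave 20 to 613 opposite genes. The log2 fold changes correlated at -0.62 across genes, against -0.50 in the simulations, with a covariance of -0.35 against -0.19. With 3 SUI libraries these could not be divided between the comparisons. How much of the excess over the simulations comes from the shared libraries therefore cannot be told.

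**Figure D3:**
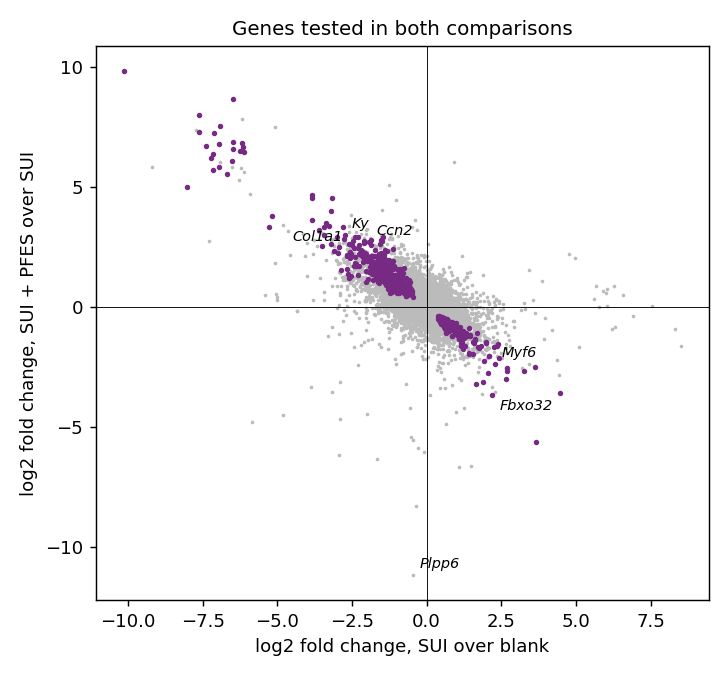
Log2 fold change of stimulated over SUI (y axis) against SUI over blank (x axis) for the 16256 genes tested. Purple points are the 556 genes with opposite signs and an unadjusted p under 0.05 in both comparisons, and grey points all other genes.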

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

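The alternatives that leave out blank replicate 1 or SUI replicate 1 in combination, sum rows by Ensembl ID or remove length trends, the count of genes opposite at unadjusted p, and camera with sample weights were chosen after seeing the data. SUI against blank kept 0 edgeR calls under the other scalings and filters, the block, the fit on 6 libraries, both FPKM fits and voom. DESeq2 called 176 there, and 132 on 8 libraries without blank replicate 1, of which 87 were shared. Leaving out one library gave 0 to 1. For stimulated against SUI, where edgeR called 2, library totals gave 1, and the fit on 6 libraries, both FPKM fits and the 7 libraries without blank 1 and SUI 1 gave 0. Plpp6 was not among the 10001 genes of the FPKM fits, so their 0 says nothing of it in either comparison. Voom with sample weights gave 48, but 2 on the 8 libraries without blank replicate 1, DESeq2 208, and DESeq2 on 8 libraries 584, and leaving out one library gave 0 to 3. For stimulated against blank, where edgeR called 1, the fit on 6 libraries, both FPKM fits and the 7 libraries gave 0, DESeq2 21, DESeq2 on 8 libraries 23, voom on 8 libraries 2, and leaving out one library 0 to 1. Opposite calls were 0 except with DESeq2 (74, and 72 on 8 libraries), and 0 to 0 leaving out one library. The 556 genes opposite at unadjusted p became 842 on 7 libraries, 1174 with voom weights and 1058 with voom on 8, and 345 to 625 leaving out one library. The cause of these shifts was not tested.

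Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.22 to 0.11, and 1 of 9 pairs was above 0.1. With the replicate block, edgeR called 0, 1 and 0 genes in the 3 comparisons.

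With an estimated correlation 0 lists were called in each comparison, against 15, 15 and 7. The filter at a mean CPM of 1 gave 15, 13 and 4, and removing length trends 12, 14 and 6. Leaving out one library gave 14 to 22, 10 to 19 and 5 to 20 lists. The 7 libraries ended the calls of atrophy genes (0.226), progenitor markers (0.0652) and mitochondrial genome (0.437) in SUI against blank, and of citric acid cycle (0.254), leukocyte (0.0557), interferon (0.058) and unfolded protein genes (0.102) in stimulated against SUI. Sample weights in camera ended calls too: mitochondrial genome (0.134), oxidative stress (0.345) and erythroid (0.0619) in SUI against blank, and citric acid cycle (0.126), leukocyte (0.0705), interferon (0.416), unfolded protein (0.0882) and glucocorticoid (0.111) in stimulated against SUI, and satellite cell markers (0.0545) in stimulated against blank. The collagen and matrix genes kept their call in both main comparisons under all 15 settings other than the estimated correlation. Over all list calls and settings, 468 values kept side and direction, 118 lost the call and 5 reversed. The reversed ones were oxidative stress response genes on 7 libraries (adjusted p = 0.931), interferon-stimulated genes without stimulated replicate 2 (0.411, with 3.61e-05 to 0.411 leaving out one library), and mitochondrial genome transcripts, stimulated against blank, without blank replicate 1 (0.495, with 0.00197 to 0.495 leaving out one library), on 7 libraries (0.399) and with voom weights (0.999).

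Single genes that reversed did not pass the threshold under those settings. In SUI against blank, on 7 libraries, Myh7 became 0.0705, Myh2 0.0884, Myh3 1.06, Trim63 -0.33, Ppargc1a 0.58 and Esr1 0.16 (log2). With voom on 8 libraries Myh2 became 0.0278, Myh3 0.65, Trim63 -0.00995 and Ppargc1a 0.45. With DESeq2 on 8 libraries Myh3 became 0.60 and Ppargc1a 0.28, with voom weights Myh3 0.56 and Ppargc1a 0.42. Leaving out one library gave Myh3 -1.25 to 0.60, Trim63 -0.0826 to 1.32 and Ppargc1a -0.48 to 0.28. Ppargc1a was 0.0312 with library totals and 0.0157 and 0.0198 in the FPKM fits. In stimulated against SUI, Myh3 became 0.14 and 0.17 in the FPKM fits, and -0.53 to 0.80 leaving out one library.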

Other observations

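The tests of the Plpp6 locus sum, of Spata6l, of the collagen and progenitor difference and of the length trend were chosen after the result was seen, as were the condition that groups overlap on the clock index and the correlation within groups. So was the count of genes opposite at unadjusted p, and with it its splits. The remaining tests were chosen before.

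Several genes not yet given for the comparison concerned passed adjusted over their list alone. Sntb1, a member of the dystrophin complex, was 2.52 log2 units lower in SUI than in blank, and the growth factor binding gene Igfbp3 was at -2.03. Among endothelial genes in the same comparison, Eng (0.82) and Nos3 (0.92) were higher and Kdr (-1.54) and Angpt1 (-1.26) lower, all adjusted over the list alone, and the list was not called as a set (camera adjusted p = 0.213). In stimulated against blank rats Greb1, an oestrogen target gene, was at -3.18 and Dkk2, a Wnt pathway regulator, at 1.26, both past the threshold adjusted over their lists alone. None of these genes passed over all genes tested. Their edgeR adjusted p there were 0.2 for Sntb1, 0.269 for Igfbp3, 0.305 for Eng, 0.504 for Nos3, Kdr and Angpt1, and 0.898 for Greb1 and Dkk2. The adjustment over a list alone does not account for the number of lists.

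Plpp6 was the only tested gene at 0 in all 3 stimulated libraries with a mean of at least 1 CPM in both other groups, and 1 gene, without a symbol, had such a pattern in SUI. The summed CPM of Plpp6 and Spata6l changed by 0.32 in log2 between SUI and stimulated rats, at 3.76 ± 0.678 after stimulation and 3.00 ± 0.968 in SUI. Spata6l alone was higher by 3.21, which argues against silencing of Plpp6 alone. Of 1331 gene pairs with overlapping spans on opposite strands, 0.0751% moved apart in this way, and the 1 pair that did was Plpp6 and Spata6l. That argues against an annotation or strand change that moves many such pairs apart. Pairs were taken by span and not by shared exons, so a change confined to pairs with shared exons cannot be judged. Given the summed CPM, reads of the locus assigned to Spata6l in place of Plpp6 may account for the Plpp6 call. Why this would occur in 1 group alone stays open.

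For the collagen and matrix genes, lower in SUI and higher after stimulation, a gene length trend is argued against, since with it removed the highest camera adjusted p of the list in the 2 comparisons was 8.00e-10 and its mean shifts were -0.95 and 1.05, against -1.03 and 1.05 before. A smaller share of connective tissue cells in the SUI samples stays possible and was not shown. From blank to SUI the collagen mean changed by -1.03 and the progenitor marker mean by -0.69. From SUI to stimulated rats they changed by 1.05 and 0.90. The collagen mean less the progenitor marker mean differed between SUI and the other 6 libraries by -0.25. That lay within the SD of 0.286 over the 9 libraries (exact permutation p = 0.262, two-sided). With 3 SUI libraries, a difference not detected does not show that both lists moved equally. Nor can this test tell a smaller share of these cells from a joint change of both lists within them. A clock phase index correlated with the collagen mean at r = -0.82 (exact permutation p = 0.00725, rho = -0.70 with p = 0.0432, 1 relation tested, and r = -0.58 without the 2 farthest libraries), past the bound set beforehand for time of day as a cause. The 3 groups do not overlap on this index, a condition added after r was seen, so time of day at collection and group cannot be told apart. Within groups the deviations gave r = -0.80 (exact permutation p = 0.255), and an effect of the model and the stimulation on matrix genes stays open too.

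Blank replicate 1 stood apart, and no biological explanation was tested for a single library. With length trends removed its median correlation with the others was 0.921, against 0.920 before and 0.949 for the lowest of the other 8 libraries, which argues against gene length bias as the whole cause. With the others thinned to its total, the lowest of the 8 was 0.954 and blank replicate 1 was at 0.929, which argues against lower depth. What set it apart stays open.

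The splits of the 6 libraries number 10 per comparison, the real one included, too few for a share under 0.05. For SUI against blank the real split called 0 genes, a count all 10 reach whatever the data (0 in the highest other), for stimulated against SUI 2 genes against 1 at most in another split (1 of 10 as large), and for stimulated against blank 1 gene against 1 (2 of 10). List calls were as many or more in 5, 7 and 10 of the 10 splits, with 15, 15 and 7 in the real split and 18, 27 and 24 in the highest other. Of 100 splits of the 9 libraries, the real one and others drawn at random, 4 gave at least 556 genes opposite at unadjusted p, the real one included. The highest gave 613. The share is under 0.05, but 4 of 100 drawn splits cannot place it firmly below that bound. Adjusted opposite calls numbered 0 in the real split, which all 100 splits reach whatever the data, with 3 in the highest other, so that this count says nothing about chance.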
